A study of Mus musculus with 18 samples.

How the data were processed

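Gene expression was measured on Illumina mouse BeadArrays in cells sorted from differentiating mouse embryonic stem cells of strain J1. Each of 3 lines carried a bacterial artificial chromosome (BAC) transgene in which the regulatory region of 1 gene drives a fluorescent protein: Hes5::GFP, Nurr1::GFP (Nurr1 is the protein made from Nr4a2) and Pitx3::YFP. All lines had been differentiated toward midbrain dopamine neurons and sorted by fluorescence (FACS) at days 14 to 15 into reporter-positive and reporter-negative cells. This gave 6 groups of 3 arrays, 18 arrays in all, numbered 1 to 3 within each group. The title and genotype of Hes5 negative replicate 2 call it GFP-negative and its source name calls it GFP-positive. It was kept as negative and its removal was tested.

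The deposited scanner table gives, per the file headers, a mean bead intensity for each of 45281 probes on a linear scale, neither background-subtracted nor normalized between arrays. Per the file headers it also holds a detection p-value, the share of negative control beads brighter than the probe. It counts in steps that correspond to 936 control bead types. The same deposited table gives the count of beads averaged for each value, at least 11. The submitters' processing notes name GenomeStudio and Partek, with no version or settings. A second deposited table holds log2 intensity for 31441 genes. Set against the scanner table, its values equal the log2 of the linear intensity of 1 probe or of the mean of several probes, so the authors took logs and averaged probes without normalizing between arrays. In this table the median of all genes is shifted by up to 0.189 log2 between groups compared. Of the scanner columns, 18 with the spread between beads were not used here.

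The scanner table carries no gene names. Probes were tied to genes by finding the 1 probe (22787 genes), the 2 probes (5163 genes) or the 3 probes (2378 genes) whose intensities give a gene's deposited values in all 18 arrays. This tied 30328 genes (96.5%), none ambiguously, while 0 of 300 shuffled value sets found a match. The remaining 1113 genes and 5034 probes stayed untied. Older symbols were updated through a table of RefSeq names for mouse (13415 matched as symbols, 6751 as synonyms, and 11275 kept as deposited). No chromosome positions are given, since no genome was used here.

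The intensities were background-corrected with the normal-exponential model fitted to the detection p-values, quantile normalized and put on the log2 scale with limma's neqc (limma 3.58.1, R 4.3.3, data.table version 1.17.8, offset 16). A probe was kept when its detection p-value was under 0.01 in at least 3 arrays, which 18737 probes were. Each gene was read from its kept probe with the highest mean, for 12650 genes tested. The 2503 kept probes without a gene were set aside. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 served for the matching, and matplotlib 3.10.9 for the plots.

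Differences were tested with limma (lmFit and eBayes, two-sided) in 1 fit of 6 group means to all 18 arrays, with 12 residual degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The comparisons were positive against negative cells within each line, the positive fractions of successive lines, the negative fractions of successive lines, and the differences of the sort effect between successive lines. Whether equal numbers mark fractions of 1 sort is not stated in the labels. The deviations of arrays from their group means correlated at 0.44 to 0.77 between positive and negative arrays of the same number in all 9 pairs, against -0.64 to 0.17 for arrays of different numbers. The numbers therefore pair the fractions, and every sort is given both without pairs and in a paired fit, which adds the replicate number within its line as a block and leaves 6 residual degrees of freedom. The lines were not paired with each other. The p-values measure the spread between these arrays alone, and nothing in the labels says whether replicates are separate differentiations. With 3 arrays a group, the number of arrays limits the precision.

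The main comparisons, 20 gene lists and the rule for named genes were fixed before the data were examined. The rule names the 3 reporter genes, the reporter itself, and Th, Slc6a3, Lmx1a, Foxa2 and Mki67 whatever their p. It adds the 10 largest rises and the 6 largest falls of each sort and positive-fraction comparison without overlap between groups, and up to 4 called members per list. Reporter RNA was read by an EGFP probe, which also reads the YFP. It leaves out RIKEN, predicted and clone names. For each difference of sort effects it names 5 genes per direction. After the pairing was found, the rule was applied again in the paired fit. The difference of the sort effects between the Pitx3 and Hes5 lines was added after the other results had been seen. The lists cover midbrain floor plate and dopaminergic progenitors, dopamine neurons, nicotinic receptor subunits, neural stem cells and radial glia, the Notch pathway, proneural and neuronal commitment, and pan-neuronal genes. Others cover the cell cycle, the Hedgehog pathway, forebrain patterning, hindbrain and Hox patterning, serotonergic neurons, motor and cholinergic neurons, and GABA neurons. The rest cover astrocytes and oligodendrocytes, pluripotency, fibroblasts and stroma, endoderm, mesoderm with muscle and endothelium, and immediate early and stress genes. The lists were tested with limma's camera (preset correlation 0.01, adjusted over the 20 lists of a comparison), again with a correlation estimated per list, and with fry.

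Where a probe was above background in no array of 1 group, fold changes are lower bounds set against the lowest normalized value with a detection p-value under 0.01 in each array. On simulated data with known changes added to the Pitx3 line, the fit without pairs called 38% of genes changed by 1 on the log2 scale and 81.2% of those changed by 2, and the paired fit 62.8% and 91.6%. Of 62250 unchanged genes, 3 were called without pairs and 44 in the paired fit, and 0 of 100 random lists were called. The simulated genes varied independently of each other, so this cannot show how often lists of genes that vary together are called falsely. The alternatives tried were the authors' deposited log2 table, quantile normalization without background correction, an offset of 50, other filters on dim probes, the mean over a gene's probes and array weights. Further ones were trend and robust variance, only the arrays compared, stricter thresholds, and leaving out each array. A block for the slide was not run, since the files give no slide.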

Results

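The 18 arrays were alike in depth. Median probe intensity lay between 40.6 and 60.2, the share of probes detected between 33.5% and 37.4%, and the mean number of beads per probe between 42.8 and 44.2. Arrays of 1 group correlated at 0.876 to 0.974 over the genes tested. The first principal component held 38.7% of the variance and the second 15.4%.

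The reporters were compared first, since they state what the sorts separated. Reporter RNA was 13.63 ± 0.09 (normalized log2 intensity, SD, n = 3) in Hes5 positive and 9.70 ± 1.33 in Hes5 negative cells, where replicate 2 read 11.12 and the other two 9.51 and 8.48. It was 11.55 ± 0.80 against 8.04 ± 0.40 in the Nurr1 line and 10.69 ± 0.63 against 6.32 ± 0.23 in the Pitx3 line. Hes5, a transcriptional repressor induced by Notch in neural progenitors, was 12.17 ± 0.26 against 10.13 ± 0.89 in its own line. In the other lines it was lower in positive than in negative cells, 9.41 ± 0.69 against 11.39 ± 0.27 in the Nurr1 line and 9.74 ± 1.4 against 12.16 ± 0.54 in the Pitx3 line. Nr4a2, the nuclear receptor needed for the dopamine neuron identity, was 10.59 ± 0.38 against 7.85 ± 0.68 in the Nurr1 line and 10.73 ± 0.75 against 7.04 ± 0.87 in the Pitx3 line. Pitx3, a homeobox factor of midbrain dopamine neurons, was 9.16 ± 1.27 against 5.06 ± 0.68 in its own line and 7.81 ± 0.38 against 5.27 ± 0.82 in the Nurr1 line. In the Hes5 line the means of both dopaminergic factors differed little between the fractions (Nr4a2 7.57 ± 1.99 against 7.18 ± 1.67, Pitx3 5.52 ± 1.42 against 5.35 ± 0.75). Pitx3 was above background there in 1 of 3 arrays of each fraction and Nr4a2 in 2, so a difference could be hidden. In replicate 2 Pitx3 read 7.14 against 6.21 and Nr4a2 9.26 against 8.23. In replicate 3 Nr4a2 read 8.07 against 8.06.

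**Figure D1:**
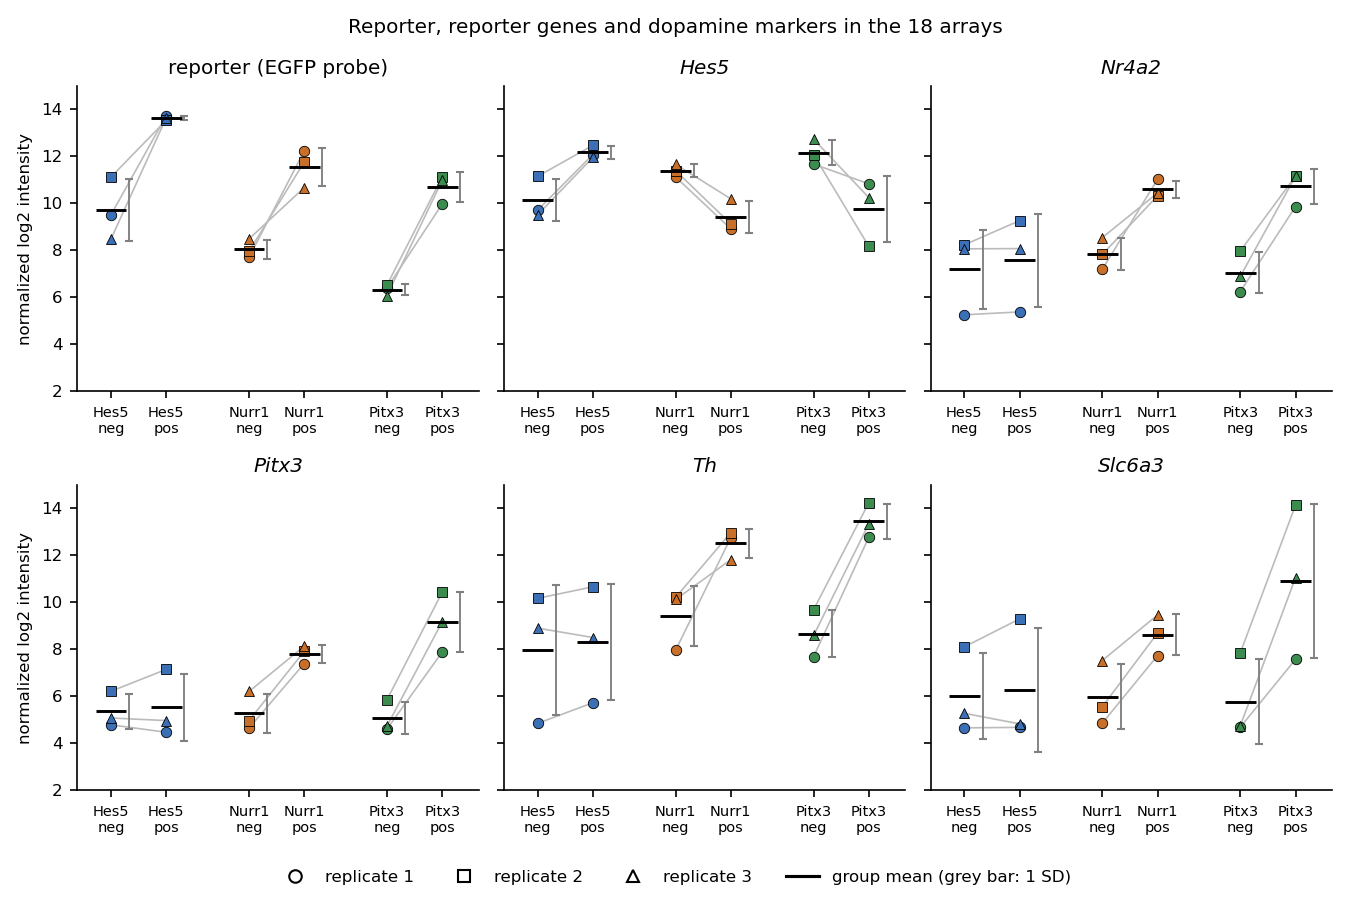
Normalized log2 intensity of the reporter and 5 genes in each array, by line and fraction, with pairs joined by grey lines, group means as black bars and 1 SD as grey bars. The reporter is higher in the positive array of all 9 pairs, and Th and Slc6a3 are higher in the positive array of each Nurr1 and Pitx3 pair.

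The comparison of Hes5 positive with Hes5 negative cells asks what marks the Notch-responsive progenitor stage. The reporter rose 15.3-fold (log2 3.93, SE 0.53, adjusted p = 0.0163, paired 0.0281, higher in 3 of 3 pairs), while Hes5 itself stood 2.04 log2 higher (SE 0.59) with an adjusted p of 0.576 without pairs and 0.0718 in the paired fit. With pairs taken into account, the neuronal commitment factors Ebf2 (log2 2.04, SE 0.28, adjusted p = 0.0281) and Myt1 (1.37, SE 0.24, 0.0448) rose, with the signalling gene Wnt7a (1.90, SE 0.37, 0.0499). So did the homeobox genes Lhx1 (1.83, SE 0.31, 0.0434), Irx5 (1.67, SE 0.30, 0.0459) and Irx3 (1.51, SE 0.20, 0.0281). St18 (1.57, SE 0.23, 0.0300), Sox2ot (1.36, SE 0.25, 0.0480) and Phf21b (1.24, SE 0.16, 0.0218) rose as well, and all 9 were higher in 3 of 3 pairs. Among the falls in the paired fit without overlap between the groups were the homeobox gene Rhox5 (-3.29, SE 0.57, adjusted p = 0.0445), the matrix proteoglycan Lum (at least 4.87-fold, 0.0459) and the matrix protein Tgfbi (-3.03, SE 0.44, 0.0300). Plac8 (at least 5.83-fold, 0.0300), Fmr1nb (at least 4.18-fold, 0.0385) and the fatty acid binding protein Fabp3 (-2.51, SE 0.37, 0.0300) fell as well, and all 6 were lower in 3 of 3 pairs. Wnt7a and Sox2ot were above background in 2 of 3 negative arrays. Without pairs none of these 15 genes passed (adjusted p 0.494 to 0.655).

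Among the dopamine lineage genes that did not pass in the Hes5 sort were Nr4a2 (0.39, paired adjusted p = 0.554), Th (0.32, 0.723), Slc6a3 (0.25, 0.84), Pitx3 (0.16, 0.793), Lmx1a (0.40, 0.468) and Foxa2 (-0.22, 0.531), and Mki67 (0.47, 0.53) did not pass either. Pitx3 and Slc6a3 were above background in 1 of 3 arrays of each Hes5 fraction, and Nr4a2, Th and Lmx1a in 2. Their changes are thus only partly measured. Without pairs 2 genes changed in the Hes5 sort, both up: the reporter and LOC327816 (at least 1.22-fold, adjusted p = 1.05e-04), a predicted gene named here after its values were seen. At an unadjusted p under 0.05 there were 822. Paired, 79 genes rose and 77 fell. The count without pairs was 97 without Hes5 negative replicate 2, whose label is contradictory, and 1 without Hes5 positive replicate 1 or 3 or Hes5 negative replicate 1 or 3. The paired count of 156 was 1128 without pair 2, 3 without pair 1, 4 without pair 3, 56, 10 and 20 without Nurr1 pairs 1, 2 and 3, and 100, 45 and 15 without Pitx3 pairs 1, 2 and 3. It was 0 by limma from the 6 arrays of the line alone and 49 with no filter on dim probes.

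Among the gene lists, 8 were called in the Hes5 sort by camera. None of these calls held with an estimated correlation, and fry called 0 without pairs. In the paired fit fry called 5, proneural (adjusted p = 0.0111), stromal (0.029), forebrain (0.0412), mesoderm (0.0412) and endoderm genes (0.0412). The proneural and neuronal commitment genes rose as a list (median 1.13, adjusted p = 5.73e-07, and adjusted p = 0.162 with an estimated correlation), with 10 of 10 members higher. Over all genes, 2 of them rose in the paired fit, Ebf2 and the basic helix-loop-helix factor Neurog2 (1.89, adjusted p = 0.0480), and 8 did adjusted over the list alone. The Notch pathway genes rose as a list (median 0.97, adjusted p = 2.00e-05, and adjusted p = 0.17 with an estimated correlation), with 9 of 10 members higher, 0 rising over all genes and 7 in the paired fit adjusted over the list alone. Hes5 is a member of this list. Neural stem cell and radial glia genes (median 0.63, adjusted p = 0.0083, 0.326 with an estimated correlation), forebrain patterning genes (1.38, 0.0144, 0.365 with an estimated correlation) and GABA neuron genes (1.80, 0.0028, 0.231 with an estimated correlation) were also called as higher. Adjusted over the list alone, 4 of 4 forebrain genes and 3 of 4 GABA neuron genes rose in the paired fit, and 0 of either over all genes.

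Pluripotency, stromal and mesoderm markers were lower in Hes5 positive cells. Pluripotency genes fell as a list (median -2.29, adjusted p = 1.23e-07, and adjusted p = 0.168 with an estimated correlation), with 10 of 10 members lower, 0 falling over all genes and 9 in the paired fit adjusted over the list alone. Fibroblast and stromal genes fell as a list (-1.90, 7.06e-07, and adjusted p = 0.162 with an estimated correlation). Of its 8 genes, Lum and Tagln (at least 1.14-fold, adjusted p = 0.0490) fell over all genes in the paired fit and 7 adjusted over the list alone. Mesoderm, muscle and endothelial genes fell as a list (-1.64, 0.0027, and adjusted p = 0.162 with an estimated correlation). The pluripotency median was 9.65, 6.16 and 8.38 in negative replicates 1 to 3 and 6.38, 6.15 and 5.81 in positive replicates 1 to 3, so pair 2 shows no fall. In that pair several members were near background in both fractions and could not fall. Utf1 read 4.95 in negative and 4.88 in positive cells, Tdh 4.92 and 4.84, and Lin28a 5.03 and 4.86. Dppa5a, at 10.08 and 9.95, was not near background. The stromal median did fall in pair 2, from 6.96 to 5.56. Dopamine neuron genes (median -0.05, adjusted p = 0.709), midbrain floor plate genes (0.18, 0.723), nicotinic subunits (0.30, 0.102) and pan-neuronal genes (0.37, 0.19) were not called. The floor plate list depends on single arrays: without negative replicate 1 it turned to -0.4 and was called (adjusted p = 0.0422), without positive replicate 1 it was called at 0.61, and neither was run with an estimated correlation. Nor were serotonergic genes (-0.28, 0.717), hindbrain genes (-0.20, 0.292), astrocyte and oligodendrocyte genes (0.82, 0.135, paired 0.0339, but paired 0.569 with an estimated correlation) and endoderm genes (-0.22, 0.195). In a further 4 lists, also not called, median, mean and test differ in sign: cell cycle genes (median 0.02, mean -0.01, 0.761), Hedgehog genes (median 0.08, test downward, 0.96), motor and cholinergic genes (median -0.21, mean 0.05, test downward, 0.772) and immediate early genes (median -0.03, test upward, 0.96). Within these lists, the motor factor Phox2a (-1.29, adjusted p = 0.0468, above background in 2 of 3 positive arrays) and the stress gene Trib3 (-1.45, 0.0480) fell in the paired fit.

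The Nurr1 sort asks what sets cells with Nr4a2 reporter activity, at the stage of commitment to the dopamine fate, apart from the rest of the culture. The reporter rose 11.4-fold (log2 3.51, SE 0.53, adjusted p = 0.0436, paired 0.0364). The nicotinic receptor subunit Chrna5 rose at least 3.62-fold (adjusted p = 0.0436, paired 0.0364). The ubiquitin ligase Pdzrn3 rose 3.71-fold (1.89, SE 0.28, 0.0436, paired 0.0364). All were higher in 3 of 3 pairs. In the paired fit Th, tyrosine hydroxylase, the rate-limiting enzyme of dopamine synthesis, rose 8.48-fold (log2 3.08, SE 0.48). Nr4a2 rose 6.71-fold (2.75, SE 0.36), and Pitx3 also rose (log2 2.55, SE 0.32). Each had an adjusted p of 0.0364 (0.568, 0.437 and 0.364 without pairs) and was higher in 3 of 3 pairs. With the same paired adjusted p and in 3 of 3 pairs rose Myrip (2.89, SE 0.37), Necab1 (2.79, SE 0.42), the vesicular glutamate transporter Slc17a6 (2.71), Pgbd5 (at least 4.53-fold), the synaptic organizer Cbln1 (2.37), Ebf3 (2.32) and Chrnb4 (1.99). The dopamine transporter Slc6a3 stood 2.65 higher (SE 0.62) with a paired adjusted p of 0.0752. Pitx3, Chrnb4 and Slc6a3 were above background in 1 of 3 negative arrays, so their sizes are approximate. Among the 15 falls in the paired fit were the adaptor gene Grb10 (-1.61, SE 0.23, 0.0364), the vesicular glutamate transporter Slc17a8 (-1.58, SE 0.23, 0.0364) and Itga11 (at least 2.14-fold, 0.0364). So were the serine synthesis enzyme Phgdh (-1.06, 0.0427), Lockd (-0.98, 0.0364) and Ccdc61 (-0.85, 0.0427).

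Without pairs 3 genes changed in the Nurr1 sort, all up, with 1051 at an unadjusted p under 0.05. Paired, 83 rose and 15 fell. The first count was 9 without Nurr1 positive replicate 3. It was 1 without any 1 Hes5 negative array, and 0 without any 1 Hes5 positive or Nurr1 negative array, without Nurr1 positive replicate 1 or 2, without Pitx3 negative replicate 1, 2 or 3, or without Pitx3 positive replicate 2. The paired count of 98 was 0 without Nurr1 pair 1 or 2, Hes5 pair 3 or Pitx3 pair 2, 1 without Pitx3 pair 3, 450 without Hes5 pair 2 and 1098 without Hes5 pair 1. It was 0 by limma with no filter on dim probes.

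Of the lists, 9 were called in the Nurr1 sort by camera, 1 of them also with an estimated correlation, though not in the paired fit. The nicotinic list was also the 1 called by fry without pairs, and the paired fit gave 3, nicotinic (adjusted p = 0.0149), dopamine neuron (0.0149) and Hedgehog genes (0.0158). Nicotinic receptor subunit genes rose (median 1.99, adjusted p = 1.35e-09, and adjusted p = 0.0089 with an estimated correlation, paired 0.219), with 5 of 5 members higher, 2 rising over all genes in the paired fit and 5 adjusted over the list alone. Dopamine neuron genes rose as a list (median 1.20, adjusted p = 1.14e-06, and adjusted p = 0.233 with an estimated correlation), with 13 of 14 members higher, 3 rising over all genes in the paired fit and 9 adjusted over the list alone. The 3 are Th, Nr4a2 and Pitx3. Pan-neuronal genes rose as a list (1.42, 1.14e-06, and adjusted p = 0.233 with an estimated correlation), with 10 of 10 members higher, 0 rising over all genes in the paired fit and 8 adjusted over the list alone.

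Progenitor programmes were lower in Nurr1 positive cells. Notch pathway genes fell as a list (median -0.96, adjusted p = 2.22e-05, and adjusted p = 0.233 with an estimated correlation), with 0 members falling over all genes and 7 of 10 in the paired fit adjusted over the list alone. Hes5 stood -1.98 lower (paired adjusted p = 0.0771). Neural stem cell genes (-0.69, adjusted p = 0.0011, 0.233 with an estimated correlation), Hedgehog pathway genes (-0.90, 8.07e-05, 0.233 with an estimated correlation) and cell cycle genes (-1.22, 1.78e-04, 0.368 with an estimated correlation) fell as lists, with all 28 members lower. Among the 28, the cell cycle gene Plk1 was above background in no Nurr1 array, so its sort effect was not measured. Mki67, a marker of cycling cells, stood -1.31 lower with a paired adjusted p of 0.111. Serotonergic neuron genes fell as a list (-1.60, 5.33e-05, and adjusted p = 0.265 with an estimated correlation), with 8 of 8 members lower. In the paired fit Slc17a8 alone fell over all genes and 7 adjusted over the list alone. Pluripotency genes also fell as a list (-1.58, 2.23e-04, and adjusted p = 0.33 with an estimated correlation), with 10 of 10 lower. Not called were the floor plate list (-0.10, adjusted p = 0.687), in which Lmx1a stood 0.87 (paired adjusted p = 0.136) and Foxa2 0.42 (0.22) higher, proneural (0.84, 0.118), forebrain (-0.68, 0.15), hindbrain (-0.20, 0.5), motor and cholinergic (0.27, 0.624) and GABA genes (-1.23, 0.0597). Nor were astrocyte and oligodendrocyte (-0.21, 0.647), stromal (-0.54, 0.0552, paired 0.0498, but paired 0.348 with an estimated correlation), endoderm (0.32, 0.118), mesoderm (-0.56, 0.151) and immediate early genes (0.01, 0.559). Ebf3, Ebf2 (1.76, paired adjusted p = 0.0390) and Ebf1 (1.1, 0.0450) rose among the proneural genes.

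The Pitx3 sort asks the same for the most mature of the 3 reporters, which marks postmitotic midbrain dopamine neurons. The reporter rose 20.6-fold (log2 4.36, SE 0.53, adjusted p = 0.0053), Ret, a receptor for glial-derived neurotrophic factors, 18.9-fold (4.24, SE 0.79, 0.0347), and Pitx3 also rose (log2 4.10, SE 0.71, 0.0248). Also without pairs, the nicotinic subunits Chrna6 (at least 5.82-fold, 0.0170), Chrna3 (2.78, SE 0.46, 0.0211) and Chrnb4 (at least 3.19-fold, 0.0280) rose. So did Ebf3 (3.28, SE 0.54, 0.0211), Myrip (3.07, 0.0377), Nrn1 (2.94, 0.0476), Slc35d3 (2.83, 0.0248) and Pgbd5 (2.72, 0.0211). The co-receptor Gfra1 (1.30, 0.0280) rose as well, and all 12 were higher in 3 of 3 pairs. Among the falls were the secreted factor Fgfbp3 (-2.85, SE 0.53, 0.0347), the ventral patterning factor Nkx2-2 (-2.70, SE 0.45, 0.0211) and Wnt7b (-2.30, 0.0413). Lrig1 (-1.96, 0.0475) and Sox2ot (at least 1.57-fold, 0.0411) fell as well, and all 5 were lower in 3 of 3 pairs. The paired fit added Th (28.0-fold, log2 4.81, SE 0.48, adjusted p = 0.0037), Slc6a3 (log2 5.16, SE 0.62, 0.0055) and Nr4a2 (12.9-fold, 3.69, SE 0.36, 0.0034), which without pairs had adjusted p of 0.0991, 0.16 and 0.0797. It also added the neuropeptide Cck (3.97, 0.0034), Necab1 (3.84, 0.0049) and Slc17a6 (3.30, 0.0064). Its largest falls were genes of serotonin neurons, the transporter Slc6a4 (-3.81, SE 0.61, 0.0126), the enzyme Tph2 (-3.29, SE 0.55, 0.0132) and the factor Fev (-3.25, SE 0.46, 0.0106). Gchfr (-3.24, 0.0075), Gata3 (-2.93, 0.0117) and the monoamine oxidase Maob (-2.87, 0.0050) fell as well, and all 6 were lower in 3 of 3 pairs. Pitx3, Slc6a3, Chrna3, Slc35d3, Pgbd5 and Gfra1 were above background in 1 of 3 negative arrays and Ret in 2, Maob in 1 of 3 positive arrays and Wnt7b and Slc6a4 in 2, so the sizes given for them are approximate.

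Without pairs 47 genes rose and 9 fell in the Pitx3 sort, with 1838 at an unadjusted p under 0.05, and in the paired fit 770 rose and 1076 fell. The count of 56 was 1489 with arrayWeights, 89 with detection required in all 3 arrays of at least 1 group, 12 with no filter on dim probes and 2 with only the arrays compared. With pairs the authors' deposited table gave 304 up and 687 down, and no filter gave 519 up and 505 down, so the excess of falls does not hold there. Slc6a3 in positive cells read 7.57, 14.14 and 11.05 in replicates 1 to 3, and Mki67 9.70, 4.97 and 7.81. Leaving out arrays, the 56 became 930 without Pitx3 positive replicate 1, 3 without Pitx3 positive replicate 2 or 3, and 4, 23 and 0 without Pitx3 negative replicates 1, 2 and 3. It was 33, 32 and 29 without Nurr1 negative replicates 1, 2 and 3, 85 and 32 without Nurr1 positive replicates 1 and 2, and 29 without Hes5 negative replicate 3. The paired count of 1846 was 40 without Pitx3 pair 2, 15 without Pitx3 pair 3, 2965 without Hes5 pair 1 and 1133 without Nurr1 pair 2.

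Of the lists, 14 were called in the Pitx3 sort by camera and 7 by fry, or 13 by fry in the paired fit, where of the 14 only pan-neuronal genes were not called. The nicotinic call alone held with an estimated correlation. Nicotinic receptor subunit genes rose (median 2.23, adjusted p = 3.32e-08, and adjusted p = 0.0212 with an estimated correlation, paired 0.24), 3 of 5 over all genes both with and without pairs, and 5 adjusted over the list alone. Dopamine neuron genes rose as a list (median 1.77, adjusted p = 1.83e-08, and adjusted p = 0.129 with an estimated correlation). Of its 14 members, 10 rose over all genes in the paired fit and 10 adjusted over the list alone, among them Ret, Th, Slc6a3 and Gfra1. Proneural genes rose as a list (1.20, 0.0248, and adjusted p = 0.306 with an estimated correlation), with 7 of 10 rising in the paired fit. Ebf2 (2.34, paired adjusted p = 0.0055), Neurod1 (at least 1.15-fold, 0.0169) and Ebf1 (1.31, 0.0106, above background in 2 of 3 negative arrays) were among them. Another 2 fell, and adjusted over the list alone 7 rose and 3 fell. Pan-neuronal genes rose as a list (0.89, 0.0111, and adjusted p = 0.459 with an estimated correlation), with 1 of 10 rising over all genes in the paired fit, and 4 rising and 1 falling adjusted over the list alone. The 1 gene is Tubb3 (0.84, 0.0201), whose probe was detected in 2 of 3 positive and 1 of 3 negative arrays.

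Genes of serotonin neurons fell in Pitx3 positive cells (median -2.87, adjusted p = 7.07e-09, and adjusted p = 0.109 with an estimated correlation), with 8 of 8 falling in the paired fit over all genes and 8 adjusted over the list alone. Gata2 (-2.81, 0.0082) and Slc17a8 (-2.73, 0.0031) are among them. Notch pathway genes fell as a list (-1.73, 3.50e-08, and adjusted p = 0.0975 with an estimated correlation), 8 of 10 over all genes in the paired fit and 9 adjusted over the list alone. They include Hes5 (-2.41, SE 0.48, 0.0180), Nrarp (-2.34, 0.0126) and Notch3 (-2.20, 0.0138). Neural stem cell genes fell as a list (-1.57, 4.67e-07, and adjusted p = 0.0975 with an estimated correlation), 6 of 8 over all genes in the paired fit and 7 adjusted over the list alone. Among them are the glutamate transporter Slc1a3 (-2.46, 0.0190), Sox9 (-2.34, 0.0179) and Nes (-2.21, 0.0157). Cell cycle genes fell as a list (-1.90, 3.50e-06, and adjusted p = 0.227 with an estimated correlation), 9 of 11 over all genes in the paired fit and 10 adjusted over the list alone. Mki67 (-2.14, 0.0175) and the mitotic kinase gene Aurkb (-2.0, 0.0184) fell with it. Hedgehog pathway genes fell as a list (-1.15, 3.75e-04, and adjusted p = 0.129 with an estimated correlation), 6 of 9 over all genes in the paired fit and 6 adjusted over the list alone. The ligand Shh (-1.92, 0.0180), Smo (-1.15, 0.0126) and Gli3 (-1.88, 0.0172) are 3 of these. Gli3 was above background in 1 of 3 positive arrays, and Notch3, Mki67 and Aurkb in 2.

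Markers of other neural regions and of glia were also lower in Pitx3 positive cells. GABA neuron genes fell as a list (median -2.06, adjusted p = 7.54e-04, and adjusted p = 0.149 with an estimated correlation). Dlx1 (-2.90, paired adjusted p = 0.0126) and the vesicular GABA transporter Slc32a1 (-2.29, 0.0206) belong to it. Forebrain genes (-1.33, 0.0214, 0.306 with an estimated correlation), hindbrain and Hox genes (-1.28, 0.011, 0.298 with an estimated correlation) and stromal genes (-0.96, 0.01, 0.306 with an estimated correlation) fell as lists. In them Dlx2 (at least 1.82-fold, 0.0359), Hoxa2 (-1.66, 0.0383), Hoxa5 (-1.69, 0.0376), Gbx2 (-1.28, 0.0323) and Pdgfrb (-0.96, 0.0456) fell in the paired fit. The stromal median did not fall in pair 1, where it was 7.12 in the positive and 6.83 in the negative array. Astrocyte and oligodendrocyte genes fell as a list (-2.0, 0.0043, and adjusted p = 0.227 with an estimated correlation), through Olig1 (-2.83, 0.0108), Aqp4 (-2.16, 0.0218) and Sox10 (-2.21, 0.0480). The floor plate list was not called (median 0.34, adjusted p = 0.535), but its members moved in opposite directions in the paired fit. Of 17, 5 rose, among them Lmx1a (1.99, SE 0.30, 0.0116), En1 (1.38, 0.0158) and Foxa2 (0.94, 0.0198). Another 3 fell, among them Spon1 (-2.32, 0.0146) and Shh. Adjusted over the list alone 6 rose and 5 fell. The motor and cholinergic list was not called (median -0.20, mean 0.05, 0.521), with Slc18a3 (1.47, 0.0152) and Chat (1.11, 0.0264) rising and Isl1 (-1.71, 0.0325) falling. Of the genes of these lists, Dlx1, Hoxa5, Gbx2, Pdgfrb and Isl1 were above background in 1 of 3 positive arrays, Slc32a1, Olig1, Sox10 and Spon1 in 2, and Slc18a3 and Chat in 1 of 3 and Sox10 in 2 of 3 negative arrays. Pluripotency (0.18, 0.883), endoderm (0.28, 0.329), mesoderm (-0.38, 0.883) and immediate early genes (-0.04, 0.772) were not called.

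**Figure D2:**
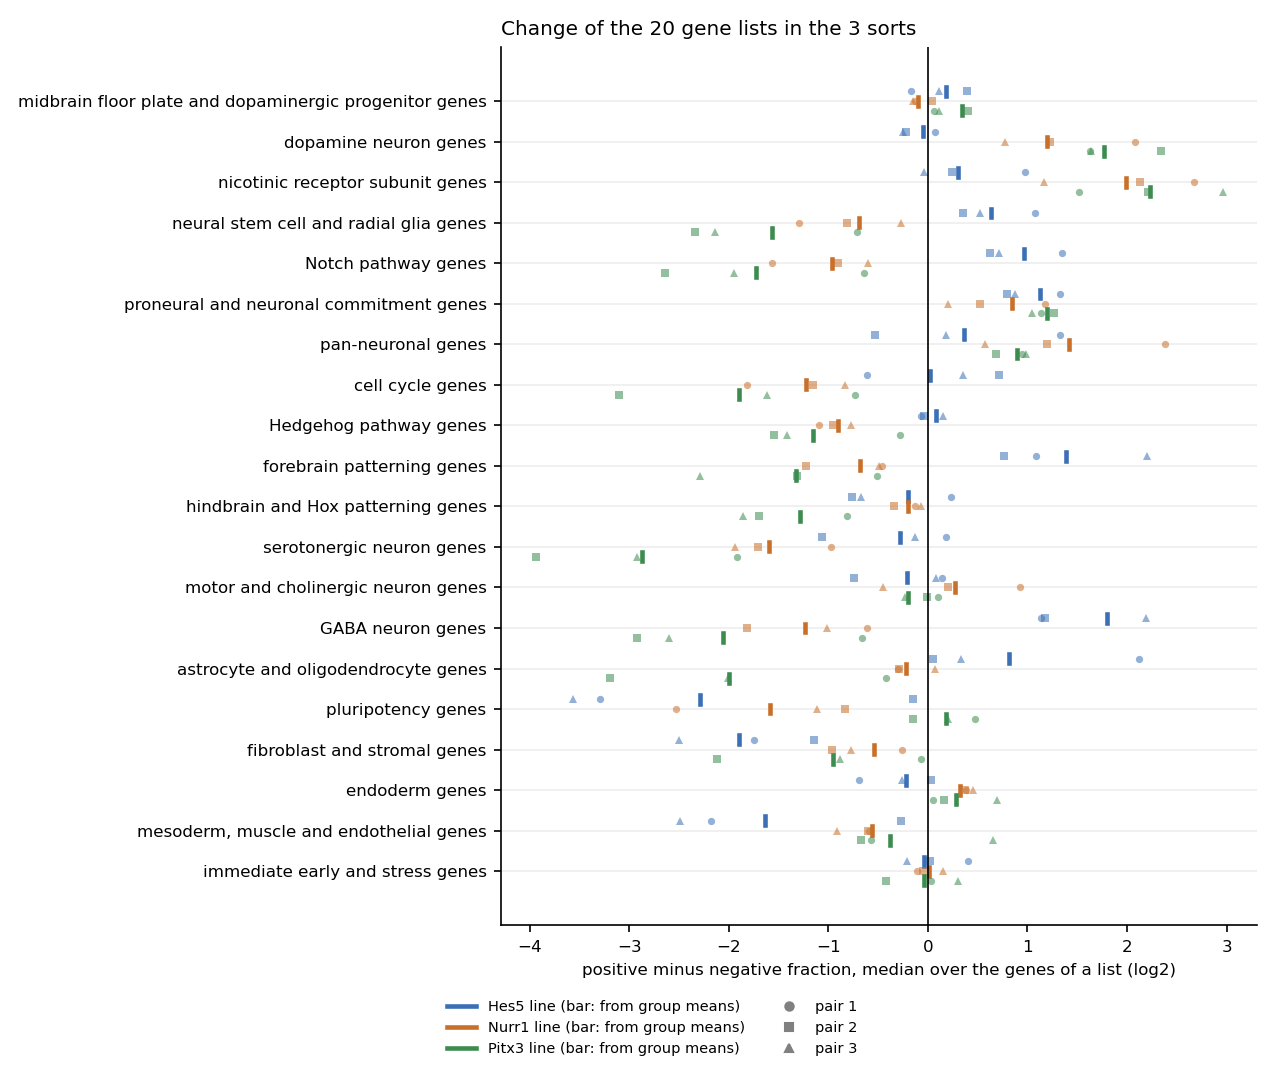
Positive minus negative fraction as the median over the genes of each of the 20 lists (log2), with a bar from the group means and a point for each pair, by line. Serotonergic genes reach -2.87 in the Pitx3 line and pluripotency genes -2.29 in the Hes5 line.

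The sort effects of the Nurr1 and Pitx3 lines were compared to ask how far both reporters pick out the same cells. Over 12650 genes, which are not independent replicates, the effects correlated (Pearson 0.79, Spearman 0.79). The highest absolute Pearson correlation of the other arrangements of the pairs was 0.73. In the paired fits 76 genes rose in both sorts, against 5.1 in independent lists, 12 fell in both, against 1.3, and 0 changed in opposite directions. The Hes5 sort correlated at 0.34 with the Nurr1 sort (Spearman 0.36) and at 0.18 with the Pitx3 sort (0.28), both below the highest of the other arrangements of the pairs (0.5 and 0.32). Hes5 and Pitx3 share 18 rises, against 4.8 in independent lists, and 8 falls, against 6.5, and 14 genes changed in opposite directions. The paired sorts take the spread of each gene from the same fit. A gene with a small spread is thus called more readily in several sorts. The numbers for independent lists therefore do not measure how much overlap coincidence would give.

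**Figure D3:**
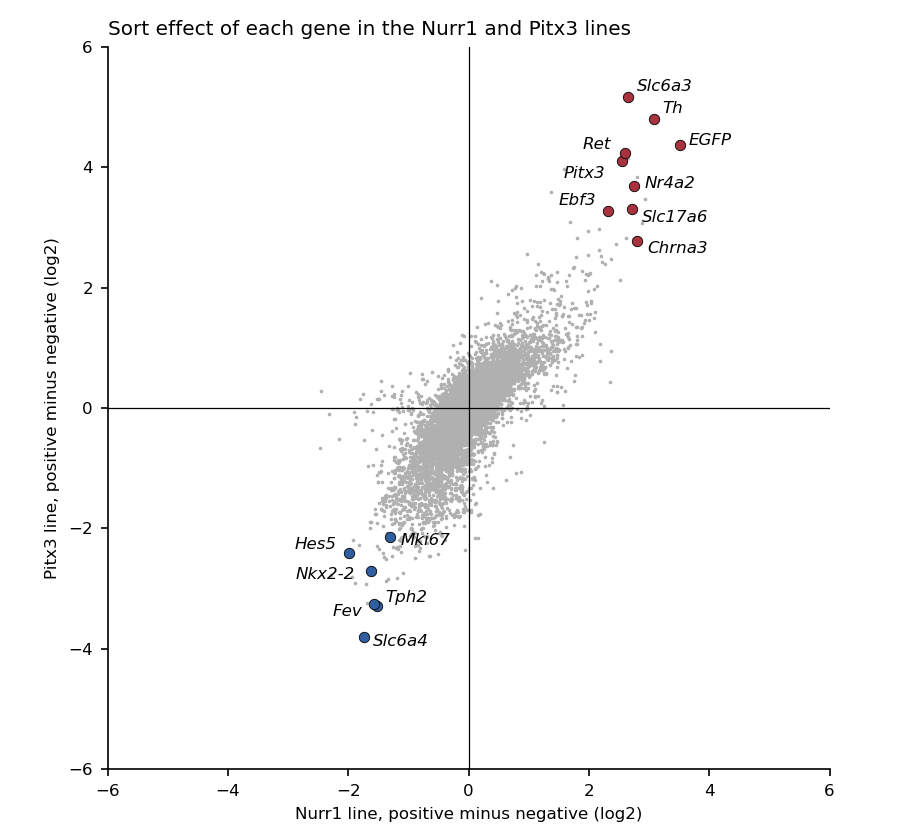
Positive minus negative log2 intensity of each of the 12650 genes in the Nurr1 line (horizontal) and the Pitx3 line (vertical), with 15 genes named. Th, Slc6a3, Nr4a2 and Pitx3 lie at the upper right, the serotonergic genes Slc6a4, Tph2 and Fev at the lower left.

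Nurr1 positive were compared with Hes5 positive cells to follow the step from progenitor to committed neuron. These fractions come from different lines, so a difference of stage cannot be told apart from a difference between lines or their cultures. This holds for every gene and list named below, also where the negative fractions do not differ. Higher in Nurr1 positive cells were Necab1 (log2 4.36, SE 0.83, adjusted p = 0.0376), Rbm11 (2.80, SE 0.56, 0.0448), the complement-related synaptic gene C1ql1 (2.73, SE 0.46, 0.0182) and Cbln1 (2.57, SE 0.50, 0.0379). So were Pgbd5 (2.28, 0.0379), Chrnb4 (1.95, 0.0499), Chrna5 (1.91, 0.0233), Timmdc1 (1.76, 0.0380), Pdzrn3 (1.56, 0.0275) and CRG-L1 (1.33, 0.0377). Lower were the glial progenitor factor Olig1 (-5.62, SE 1.15, 0.0493), Pou6f1 (at least 16.5-fold, 1.89e-08) and Grb10 (-5.16, SE 0.31, 3.99e-07). So were the mitotic kinase gene Plk1 (at least 15.8-fold, 1.88e-04), Slc32a1 (-3.87, SE 0.64, 0.0182) and Wnt7a (at least 6.52-fold, 0.0078). Pou6f1, Grb10 and Plk1 also differed between the negative fractions, so theirs are not specific to this step. Timmdc1 (9.69, 9.61 and 9.42 in Nurr1 negative, 7.41, 8.6 and 7.35 in Hes5 negative replicates 1 to 3), CRG-L1 (7.5, 6.99 and 6.83 against 6.52, 6.51 and 6.32) and Olig1 (5.64, 8.27 and 8.22 against 11.43, 10.64 and 9.93) were apart there in the same direction without passing, so these 3 cannot be assigned to the step either. Th (4.22, SE 1.26, 0.169), Nr4a2 (3.03, SE 0.89, 0.168) and Pitx3 (2.29, SE 0.71, 0.188) stood higher and Hes5 (-2.76, SE 0.59, 0.0543) lower without passing. Th, Nr4a2 and Pitx3 stood 2.93, 1.93 and 1.76 higher without Hes5 positive replicate 1, and without Hes5 positive replicate 2 all 3 passed. Necab1, Rbm11, C1ql1, Pgbd5, Chrnb4, Chrna5 and Pitx3 were above background in 1 of 3 Hes5 positive arrays and Th and Nr4a2 in 2, Slc32a1 in 1 of 3 Nurr1 positive arrays and Olig1 in 2. Altogether 13 genes were higher and 40 lower, with 1728 at an unadjusted p under 0.05. Without Hes5 positive replicates 1, 2 and 3 the 53 became 12, 335 and 16, and without Nurr1 positive replicates 1, 2 and 3 19, 15 and 33. The count was 118 and 35 without Pitx3 positive replicates 1 and 3, 92 and 32 without Hes5 negative replicates 2 and 3, and 31 without Nurr1 negative replicate 2. Without both arrays of Hes5 pair 1 there were 13, with arrayWeights 297, with no filter 18 and with only the arrays compared 8.

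Of the lists, 13 were called between these positive fractions by limma's camera and 10 by fry. With an estimated correlation camera called 0 (smallest adjusted p 0.0677). Dopamine neuron genes were higher in Nurr1 positive cells (median 1.48, adjusted p = 1.17e-05, and adjusted p = 0.177 with an estimated correlation), as were nicotinic subunits (1.91, 1.17e-05, and adjusted p = 0.0677 with an estimated correlation). So were endoderm genes (1.52, 7.96e-05, and adjusted p = 0.0677 with an estimated correlation), pan-neuronal genes (0.96, 1.47e-04, 0.264 with an estimated correlation) and floor plate genes (0.67, 0.033, 0.563 with an estimated correlation). The floor plate median was low in Hes5 positive replicate 1 only: it was 7.66, 10.29 and 10.05 in Hes5 positive replicates 1 to 3 and 10.59, 10.25 and 9.76 in Nurr1 positive replicates 1 to 3. The call was not tested without that array. Between the negative fractions, floor plate (0.83, adjusted p = 8.70e-04, 0.559 with an estimated correlation), cell cycle (-0.34, 0.0312, 0.663 with an estimated correlation), serotonergic (-0.63, 0.0437, 0.663 with an estimated correlation) and glial genes (-0.54, 0.0182, 0.559 with an estimated correlation) were called in the same direction. The 11 cell cycle genes include Plk1, which was above background in no Nurr1 array. It stood at -4.62 (SE 0.48) there and at -4.75 between the positive fractions. Mki67 averaged 10.01 in Nurr1 negative and 9.94 in Hes5 negative cells. The cell cycle calls were not tested without Plk1, so they may rest on it. Endoderm genes stood 0.87 higher there (0.104), with medians of 6.14, 7.82 and 8.70 in Nurr1 negative and 6.0, 8.11 and 9.15 in Nurr1 positive replicates 1 to 3. The differences of these lists can thus not be assigned to the step in full. For floor plate genes the median was no larger between the positive fractions (0.67) than between the negative (0.83). It was larger between the positive fractions for cell cycle (-1.63 against -0.34), serotonergic (-1.77 against -0.63), glial (-1.51 against -0.54) and endoderm genes (1.52 against 0.87). Whether this excess belongs to the step was not tested. Lmx1a stood 3.16 (adjusted p = 0.358), Foxa2 1.52 (0.238) and Slc6a3 2.37 (0.546) higher, which became 1.01, 0.77 and 1.57 without Hes5 positive replicate 1. In Hes5 positive arrays Lmx1a was above background in 2 of 3 and Slc6a3 in 1 of 3. Without Hes5 positive replicate 2 Foxa2 passed, at 2.1. Mki67 (-1.70, 0.385) and the reporter (-2.08, 0.114) stood lower without passing. Lower were GABA neuron genes (-3.25, 7.96e-05, 0.0996 with an estimated correlation), forebrain genes (-2.42, 6.88e-05, 0.0996 with an estimated correlation), and Notch genes (-1.52, 5.66e-07, 0.091 with an estimated correlation). So were neural stem cell genes (-1.24, 8.14e-06, 0.091 with an estimated correlation) and cell cycle genes (-1.63, 2.63e-06, 0.173 with an estimated correlation). The others were serotonergic genes (-1.77, 1.17e-05, 0.167 with an estimated correlation), glial genes (-1.51, 2.22e-04, 0.117 with an estimated correlation) and Hedgehog genes (-0.65, 1.45e-04, 0.0996 with an estimated correlation).

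Pitx3 positive were compared with Nurr1 positive cells to follow the step toward the mature neuron. Here too, line and stage cannot be told apart. The dopamine neuron genes were higher as a list in Pitx3 positive cells (median 1.1, adjusted p = 3.03e-06, and adjusted p = 0.512 with an estimated correlation), with 13 of 14 members higher, 0 over all genes and 3 adjusted over the list alone. Pitx3 stood 1.35 higher (SE 0.71, adjusted p = 0.974), Th 0.94 (SE 1.26, 0.993) and Slc6a3 2.29 (SE 1.57, 0.981), while Nr4a2 differed by 0.13 (SE 0.89, 0.999). Hes5 (0.34, 0.994), Lmx1a (-0.33, 0.997), Foxa2 (-0.14, 0.997), Mki67 (-1.21, 0.981) and the reporter (-0.87, 0.979) did not pass either. Neural stem cell genes (-0.67, 0.0048, 0.512 with an estimated correlation) and cell cycle genes (-0.95, 0.0099, 0.829 with an estimated correlation) were lower as lists. So were hindbrain genes (-0.76, 0.041, 0.784 with an estimated correlation) and endoderm genes (-0.33, 0.0048, 0.38 with an estimated correlation), and motor and cholinergic genes were higher (0.58, 0.041, 0.784 with an estimated correlation). Single arrays weigh on these lists: cell cycle medians were 9.70, 5.03 and 7.92 in Pitx3 positive replicates 1 to 3 and 8.80, 8.75 and 8.78 in Nurr1 positive, those of neural stem cell genes 9.15, 6.44 and 8.08 and 8.47, 9.17 and 9.73. Hindbrain medians were 6.61, 5.39 and 5.47 and 5.75, 7.03 and 6.91, those of motor and cholinergic genes 8.02, 4.92 and 5.88 and 6.09, 6.46 and 5.06. Endoderm medians were 5.46, 5.83 and 5.69 and 6, 8.11 and 9.15. In negative replicates 1 to 3 they were 5.67, 5.67 and 5 in the Pitx3 and 6.14, 7.82 and 8.7 in the Nurr1 line. The endoderm difference is thus not particular to the positive fractions. Without Pitx3 positive replicate 2 Mki67 differed by 0.05, and the lists were not tested without it. Only 2 genes changed, with 643 at an unadjusted p under 0.05: Grb10 (4.27, SE 0.31, adjusted p = 1.13e-05) and the Y-linked gene Eif2s3y (at least 7.08-fold, 0.0063). The count was 1 without Nurr1 positive replicate 1 or 2 or Pitx3 positive replicate 2 or 3.

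The negative fractions were compared as a background for the lines. Pitx3 negative and Nurr1 negative cells differed in the same 2 genes, Grb10 (log2 3.03, SE 0.31, adjusted p = 0.0011) and Eif2s3y (at least 6.94-fold, 0.0092), with 472 at an unadjusted p under 0.05. The count was 1 without any 1 Nurr1 negative array or without Pitx3 negative replicate 2 or 3. Between Nurr1 negative and Hes5 negative cells 7 genes changed, all lower in the Nurr1 line, with 819 at an unadjusted p under 0.05 and 240 called without Hes5 negative replicate 2. They were Pou6f1 (at least 7.84-fold, adjusted p = 6.61e-07), Plk1 (at least 16.6-fold, 3.31e-04), Grb10 (-3.40, SE 0.31, 1.22e-04) and Picalm (-3.17, SE 0.35, 5.11e-04). The others were D830030K20Rik (-2.71, 2.44e-04), Arhgap12 (-2.28, 0.0160) and the protease Ctsc (at least 1.86-fold, 0.0036), named here after their values were seen. All 7 were also lower in Nurr1 positive than in Hes5 positive cells. Of the lists, 9 were called between Nurr1 negative and Hes5 negative cells and 11 between Pitx3 negative and Nurr1 negative cells, 0 with an estimated correlation in either (smallest adjusted p 0.559 and 0.334). The largest median shift of these was that of serotonergic genes, 1.82 higher in Pitx3 negative cells (adjusted p = 4.85e-08, and adjusted p = 0.334 with an estimated correlation).

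**Figure D4:**
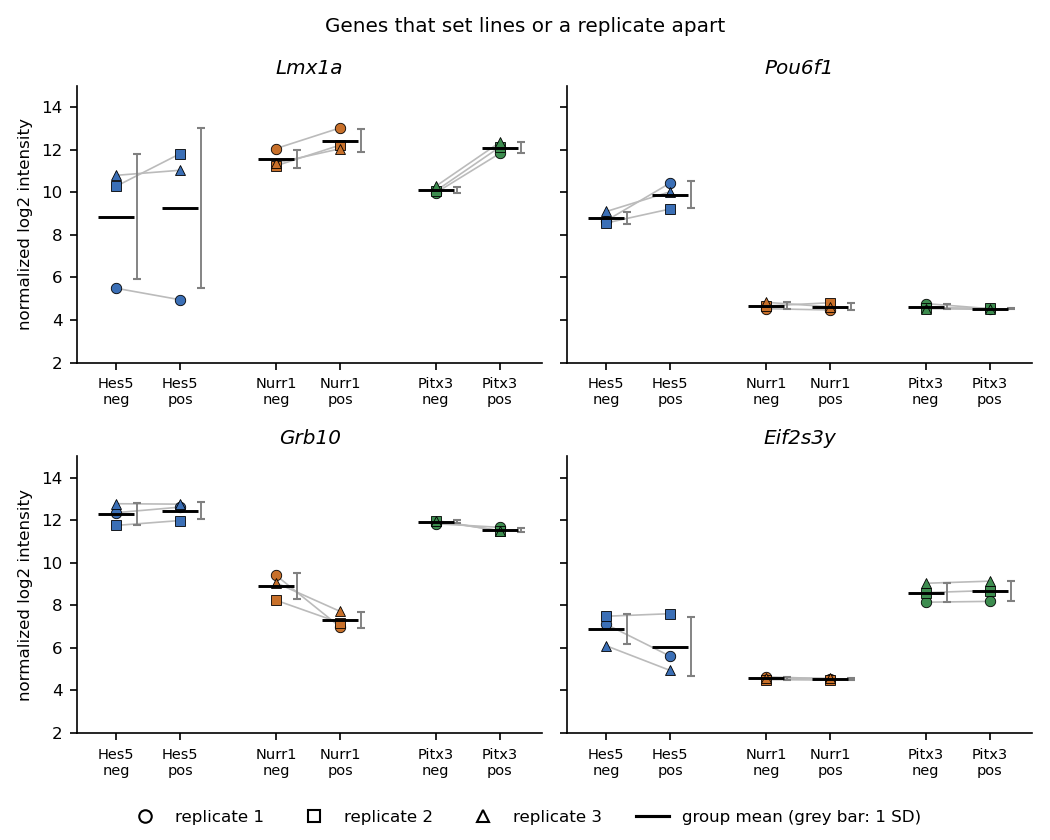
Normalized log2 intensity of 4 genes in each array, by line and fraction, with pairs joined by grey lines, group means as black bars and 1 SD as grey bars. Lmx1a reads 4.95 and 5.49 in replicate 1 of the Hes5 line, Pou6f1 is highest in the Hes5 line, Grb10 lowest in the Nurr1 line, and Eif2s3y is near background in all 6 Nurr1 arrays.

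The differences of the sort effects ask which genes a reporter separates more than the one before it. Between the Nurr1 and Hes5 sorts, Notch pathway genes differed downward (median -1.50, adjusted p = 5.96e-12, and adjusted p = 0.037 with an estimated correlation, paired 0.16). Nicotinic subunits differed upward (1.63, 2.63e-06, and adjusted p = 0.037 with an estimated correlation, paired 0.16). Of the lists 13 were called, and only these 2 with an estimated correlation. Proneural genes (-0.64, adjusted p = 0.02, 0.338 with an estimated correlation) lost the call in the paired fit (0.0679), and glial genes (-1.22, 0.0722) gained it (0.0181, but 0.373 with an estimated correlation). Hes5 differed by -4.03 (SE 0.83, adjusted p = 0.429, paired 0.0705), Cdc25b by -2.27 (SE 0.47, 0.429, paired 0.0607), Sox2ot by -2.49 (0.211, paired 0.0607), Btbd17 by -1.79 (0.429) and Tmem168 by -1.58 (0.429). Upward came Cbln1 (2.81, SE 0.71, 0.674), Rps6kl1 (2.02, 0.674), Chrna5 (1.89, 0.674), Ydjc (1.76, 0.674) and Mtss1 (1.14, 0.739). Chrna5, Btbd17 and Tmem168 were above background in no array of at least 1 group compared, so their sizes are approximate. By limma 1 gene passed, LOC327816 (adjusted p = 0.0146, paired 0.0607), whose probe was above background in Hes5 positive cells but in no Nurr1 array, with 505 at an unadjusted p under 0.05. The paired fit called 0, with 1917 at an unadjusted p under 0.05. Without Nurr1 positive replicate 3 there were 2, and 0 without Nurr1 positive replicate 2, any 1 Nurr1 negative array or Hes5 negative replicate 2 or 3.

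Between the Pitx3 and Nurr1 sorts no gene differed by limma (0 without pairs and 0 in the paired fit, with 56 and 480 at an unadjusted p under 0.05). Among the genes with the smallest p were upward Chrna6 (2.23, SE 0.76), Inpp4b (1.29), Bmp5 (1.27), Mef2d (0.66) and Ppm1j (0.66), and downward Mt3 (-1.71, SE 0.58), Nfia (-1.32), Prkg2 (-1.29) and TNS (-1.01), with a paired adjusted p of 0.999 for each. Chrna6, Inpp4b, Mef2d and TNS were above background in no array of at least 1 group compared, so their sizes are approximate. Of the lists, 10 were called and 0 by camera with an estimated correlation (smallest adjusted p 0.261), and fry called 0. The paired fit called 13, adding floor plate (median 0.29, adjusted p = 0.0304), proneural (0.24, 0.0304) and forebrain genes (-0.80, 0.0444). None of its calls held with an estimated correlation (0.342, 0.368 and 0.368 for these 3), and fry called 0 there as well. Pluripotency genes differed by a median of 1.63 (adjusted p = 1.55e-06, and adjusted p = 0.261 with an estimated correlation), serotonergic genes by -1.30 (2.78e-06, 0.261 with an estimated correlation) and dopamine neuron genes by 0.75 (1.92e-04, 0.352 with an estimated correlation). Pluripotency medians were 7.17, 5.32 and 5.48 in Pitx3 negative and 7.82, 4.77 and 5.68 in Pitx3 positive replicates 1 to 3. In the Nurr1 line they were 7.42, 7.08 and 7.02, and 5.27, 5.52 and 5.62. In Pitx3 negative replicates 2 and 3 the median was thus near background and had little room to fall. The difference of 1.63 may reflect this limit.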

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

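The split tests were fixed before any other split had been computed, though the paired fits and the difference Pitx3 minus Hes5 they apply to were themselves taken up after the first results. The split test of the shared sort effect and all tests of single patterns were chosen after the results were seen. With 3 arrays a group there are only 10 ways to split the 6 arrays of a comparison, 4 that part every pair, and 16 arrangements for the shared sort effect. So few splits leave the tests without the power to exclude a coincidence, and only the counts are given. For genes changed without pairs, the labelled split of the Hes5 sort gave 2 genes and the highest other split 47, with 5 of 10 splits giving at least as many. For the Nurr1 sort these were 3, 0 and 1 of 10, for the Pitx3 sort 56, 25 and 1 of 10, and for Nurr1 positive versus Hes5 positive cells 53, 0 and 1 of 10. For Pitx3 positive versus Nurr1 positive cells they were 2, 41 and 3 of 10, for the negative fractions 7, 14 and 2 of 10 (Nurr1 versus Hes5) and 2, 0 and 1 of 10 (Pitx3 versus Nurr1). For the differences of sort effects they were 1, 0 and 1 of 10 (Nurr1 minus Hes5), 0, 1 and 10 of 10 (Pitx3 minus Nurr1) and 7, 0 and 1 of 10 (Pitx3 minus Hes5).

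In the paired fit the labelled split gave 156 genes in the Hes5 sort, 98 in the Nurr1 sort and 1846 in the Pitx3 sort, the highest of the other splits that part every pair gave 0 in each, and 1 of 4 splits gave as many. For the paired difference Pitx3 minus Hes5 the labelled value was 414 and the highest other 0, with 1 of 10 as large. Gene lists called were 8 against 9 in the Hes5 sort (2 of 10 splits with at least as many), 9 against 8 in the Nurr1 sort (1 of 10) and 14 against 12 in the Pitx3 sort (1 of 10). For the shared sort effect of Nurr1 and Pitx3 the correlation was 0.79 against 0.73, with 1 of 16 as large. For Hes5 and Nurr1 it was 0.34 against 0.5, with 4 of 16 as large, and for Hes5 and Pitx3 0.18 against 0.32, with 5 of 16. The Hes5 split with 47 genes sets positive replicates 1 and 3 and negative replicate 3 against the rest, and so parts 1 pair. That points to a structure among the samples beside the sort. The variation due to replicate number was not compared with that due to the sort. The Pitx3 split with 25 genes, positive replicate 1 with negative replicates 1 and 2, also parts 1 pair. The split with 41 genes between positive fractions sets Pitx3 positive replicate 1 with Nurr1 positive replicates 2 and 3 against the rest, so a structure among the samples exceeds the difference of the lines there. Among the 4 splits that part all 3 pairs, those other than the labelled one gave 0 genes in each sort without pairs.

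A group of 7 genes, Arhgap12, Ctsc, D830030K20Rik, Grb10, Picalm, Plk1 and Pou6f1, is lower in the Nurr1 than in the Hes5 line in both fractions. All but Grb10 are low in the Pitx3 line as well, such as Plk1 (5.31 and 5.11 in negative and positive cells) and Pou6f1 (4.63 and 4.53). These set the Hes5 line apart from both others. Grb10 alone is high in the Pitx3 line (11.93 and 11.56). The largest sort effect in any line was, in the median gene, 0.15 of the difference between the lines. The genes were chosen for differing in both fractions, which largely builds in a small share. A different cell stage or makeup of the whole culture would shift both fractions, so the share cannot decide on that explanation. For genes with another detected probe (Ctsc, D830030K20Rik and Grb10), that probe was lower by a median of 0.98 log2 (-0.98, -0.75 and -2.52), less than the probe used. A probe that reads differently in a line could thus account for part of the difference. For the 4 genes with 1 detected probe, Arhgap12, Picalm, Plk1 and Pou6f1, this could not be tested with another probe. Plk1 read 5.23, 5.39 and 5.07 in Nurr1 negative and 11.03, 8.46 and 10.07 in Hes5 negative replicates 1 to 3. Other cell cycle genes did not follow it: Top2a read 11.08, 10.45 and 10.01 against 11.53, 9.98 and 11.31. Mki67 averaged 10.01 against 9.94. The Plk1 folds given above may thus reflect its probe and not the gene.

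In both arrays of Hes5 replicate 1, Lmx1a (4.95 and 5.49 in positive and negative cells), Th (5.72 and 4.84) and Nr4a2 (5.37 and 5.25) are near background, 3 genes picked after their values were seen. Of the floor plate list, Msx1 (6.1 and 5.81), Rspo2 (4.46 and 4.63) and Wnt1 (4.94 and 4.76) are low there as well. The pattern is thus not limited to the genes picked. Other midbrain genes are expressed, such as En1 (10.26 and 9.34) and En2 (10.58 and 9.26). The median of the floor plate list is 7.66 and 7.71. In replicates 2 and 3 it is 10.29 and 10.05 in positive and 9.4 and 9.93 in negative cells. Arrays of another line under a Hes5 label are unlikely, since 5 of 5 genes that mark the Hes5 line were higher in both arrays than in every array of the other lines. Leftover pluripotent cells in place of neural cells are also unlikely in the positive array, whose pluripotency median stood at -2 log2 relative to Hes5 negative replicate 3. In the negative array the pluripotency median was 9.65, against 6.16 and 8.38 in negative replicates 2 and 3. Its pan-neuronal median was 9, below the 11.06 of replicate 2 and 0.19 above the 8.81 of replicate 3. For the negative array, leftover pluripotent cells are thus left open as part of the pattern. Another regional identity of the culture (hindbrain or forebrain) is possible and was not settled: relative to the other replicates, hindbrain genes stood at 2.35 in the positive but -0.11 in the negative array, and forebrain genes at 0.1 and 0.3.

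The contradictory label of Hes5 negative replicate 2 was tested as well. That the array holds the positive fraction is unlikely, since its reporter read -2.42 log2 relative to the lowest positive array. Reporter-positive cells left in the negative fraction may explain part of it: its reporter reached 18.7% of the positive array, against 5.36% and 2.8% in the other pairs. The 127 genes at least 1 log2 higher in both other pairs rose by a median of 0.34 in this pair against 1.57, a share of 0.21, and the 317 at least 1 log2 lower changed by -0.33 against -1.94, where genes so selected for pairs 1 and 3 gave 1.41 against 1.44 and 1.04 against 1.66 (higher) and -1.29 against -1.79 and -1.85 against -1.59 (lower). Such cells alone, at the level the reporter gives, would leave a share of 0.71 (1.12 log2). The observed share of 0.21 is lower, so they do not account for the whole of the small rise in this pair. The test left open whether they account for a part. For the lower genes no expected share was computed. Some of them are pluripotency genes that were near background in both arrays of this pair and so could not fall. Utf1, at -4.08 and -3.58 in pairs 1 and 3, read 4.95 and 4.88 here in negative and positive cells.

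Other results stand apart from the planned account. LOC327816 was the 1 gene whose sort effect differed between the Nurr1 and Hes5 lines without pairs (fitted at -1.52 log2), a call that ends in the paired fit (adjusted p = 0.0607), and its probe was above background in Hes5 positive cells alone of these 4 groups, so the size was not measured. Between the Pitx3 and Hes5 lines, a comparison added later, 7 genes differed without pairs and 414 in the paired fit. Of the 20 lists, 13 were called in the difference Nurr1 minus Hes5, 10 in Pitx3 minus Nurr1 and 12 in Pitx3 minus Hes5, and with an estimated correlation 2, 0 and 3. Among the 2503 detected probes tied to no gene, 470 changed in the Pitx3 sort in the paired fit (217 up, 253 down), 52 in the Nurr1 sort and 13 in the Hes5 sort, so part of the response has no gene name here.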

How the results depend on the processing

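How far single genes kept direction and side of the threshold depended on the setting. In the replicate block 105 values of named genes kept both and 92 gained the call, and with arrayWeights 139 kept both and 51 gained it. With only the arrays compared 162 kept both and 34 lost the call. Leaving out 1 array kept 1071, lost 156, gained 39 and moved 36. Among the named genes 178 values kept both in the authors' deposited table, 190 with quantile normalization without background correction, 186 with an offset of 50 and 165 with no filter, where 32 lost the call. The 60 list results of the sorts kept both in 57 cases in the authors' table, and in 60 with the mean over probes. The counts of genes did not. In the simulated data 2.4% of genes changed by 0.5 log2 were called without pairs and 12.4% in the paired fit. The share of probes above background was 33.5% to 37.4%, and what depth limits was not tested. Where no cause is given here, the cause was not tested. A block for the slide was not run, since the files give none.

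No filter on dim probes tests more genes. Without pairs it gave 1 gene in the Hes5 sort, 0 in the Nurr1 sort, 12 in the Pitx3 sort, 18 between Nurr1 and Hes5 positive cells, 1 between Pitx3 and Nurr1 negative cells and 1 in the difference of sort effects Pitx3 minus Hes5. In the paired fit it gave 49 (Hes5), 0 (Nurr1), 1024 (Pitx3, 519 up and 505 down) and 67 (Pitx3 minus Hes5). Requiring detection in all 3 arrays of at least 1 group gave 89 in the Pitx3 sort. With only the arrays of the groups compared, which leaves 4 degrees of freedom in a sort, the counts were 0 (Hes5 sort), 0 (Nurr1 sort), 2 (Pitx3 sort), 8 (Nurr1 against Hes5 positive), 1 (Nurr1 against Hes5 negative), 1 (Pitx3 against Nurr1 negative), 0 (Nurr1 minus Hes5) and 0 (Pitx3 minus Hes5). With arrayWeights they were 4, 44 and 1489 in the Hes5, Nurr1 and Pitx3 sorts, 297 between Nurr1 and Hes5 positive cells, 8 between Pitx3 and Nurr1 positive cells, 17 between Nurr1 and Hes5 negative cells and 220 for Pitx3 minus Hes5. These weights are estimated gene by gene and depend slightly on the order of the genes. At an adjusted p under 0.01 they were 1, 0 and 3 in the 3 sorts, 15 between Nurr1 and Hes5 positive cells, 0 for Nurr1 minus Hes5 and 0 for Pitx3 minus Hes5, and in the paired fit 2, 0 and 65 in the sorts and 0 for Pitx3 minus Hes5.

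The authors' deposited table gave 0 in the Nurr1 sort, 0 for Nurr1 minus Hes5 and 0 for Pitx3 minus Hes5, and in the paired fit 289 in the Hes5 sort (94 up, 195 down), 289 in the Nurr1 sort (214 up, 75 down) and 991 in the Pitx3 sort (304 up, 687 down). Quantile normalization without background correction gave 0 in the Nurr1 sort and 0 for Nurr1 minus Hes5. An offset of 50 gave 0 in the Nurr1 sort, 0 for Nurr1 minus Hes5, 2 for Pitx3 minus Hes5 (0 up, 2 down) and 100 in the paired Hes5 sort. Trend and robust variance gave 0 in the Nurr1 sort, 0 for Nurr1 minus Hes5 and 0 for Pitx3 minus Hes5.

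The replicate block within lines, the paired fit, gave 156, 98 and 1846 in the Hes5, Nurr1 and Pitx3 sorts, 0 for Nurr1 minus Hes5 and 414 for Pitx3 minus Hes5. Of the 60 list results of the sorts, camera gained 2 calls in it, those of glial genes in the Hes5 sort and stromal genes in the Nurr1 sort, both lost there with an estimated correlation (0.569 and 0.348), and fry rose from 0, 1 and 7 calls to 5, 3 and 13. Between lines the samples share only a number: 6 of 18 same-number correlations were over 0.1, and a block for the number gave 162 between Nurr1 and Hes5 positive cells. With an estimated correlation 2 of the 31 list calls of the sorts remained, and with fry 8.

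Chosen after the data were seen were the following alternatives. The authors' table after quantile normalization gave 0 for Nurr1 minus Hes5 and 249 in the paired Nurr1 sort. Without both arrays of Hes5 pair 1 there were 1 in the Hes5 sort, 13 between Nurr1 and Hes5 positive cells, 0 for Nurr1 minus Hes5 and 0 for Pitx3 minus Hes5. The paired results became, with no replicate block, 2, 3 and 56 in the sorts and 7 for Pitx3 minus Hes5. With only the arrays of the lines compared they were 0 in the Hes5 sort and 3 for Pitx3 minus Hes5. At 2-fold or more they were 96 in the Hes5 and 885 in the Pitx3 sort.

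Leaving out each array in turn gave 1 to 97 genes in the Hes5 sort, 0 to 9 in the Nurr1 sort, 0 to 930 in the Pitx3 sort, 12 to 335 between Nurr1 and Hes5 positive cells, 1 to 3 between Pitx3 and Nurr1 positive cells, 6 to 240 between Nurr1 and Hes5 negative cells and 1 to 2 between Pitx3 and Nurr1 negative cells. It gave 0 to 2 for Nurr1 minus Hes5, 0 to 0 for Pitx3 minus Nurr1 and 0 to 139 for Pitx3 minus Hes5. Leaving out each pair in turn gave in the paired fit 3 to 1128 (Hes5), 0 to 1098 (Nurr1), 15 to 2965 (Pitx3) and 0 to 658 (Pitx3 minus Hes5). List calls of the sorts were 29 to 36, and the shared correlation 0.63 to 0.84. The midbrain floor plate list of the Hes5 sort ranged from -0.4 to 0.61, and reversed to -0.4 without Hes5 negative replicate 1 (adjusted p = 0.0422, not run with an estimated correlation).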

Other observations

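The sort effects of the Pitx3 and Hes5 lines, the latest and the earliest reporter, were compared after the other results had been seen. In the paired fit the dopaminergic genes Slc6a3 (difference 4.91 log2, SE 0.87, adjusted p = 0.0311), Ret (4.86, SE 0.68, 0.0222), Th (4.48, SE 0.68, 0.0231), Pitx3 (3.93, SE 0.45, 0.0177) and Nr4a2 (3.30, SE 0.50, 0.0231) differed upward, with the neuropeptide Cck (4.83, SE 0.52, 0.0177). Slc6a3 and Pitx3 were above background in 1 of 3 arrays of each Hes5 fraction and of Pitx3 negative cells. Th and Nr4a2 were in 2 of 3 arrays of each Hes5 fraction, so these sizes are approximate. Among those differing downward were Hes5 (-4.46, SE 0.68, 0.0231) and the Notch target Nrarp (-3.80, SE 0.54, 0.0222). Without pairs 7 genes passed, among them Fgfbp3 (-4.53, SE 0.76, adjusted p = 0.0472) and Wnt7b (-4.15, SE 0.65, 0.0465). The paired fit called 161 upward and 253 downward.

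Of the lists, 12 were called for this difference. Notch pathway genes (median -2.36, adjusted p = 2.18e-13, and adjusted p = 0.0288 with an estimated correlation), neural stem cell genes (-2.01, 7.52e-10, and 0.0288 with an estimated correlation) and nicotinic subunits (1.60, 2.26e-05, and 0.0426 with an estimated correlation) held in both tests without pairs. For this difference the estimated correlation was not run in the paired fit, where the like calls of Nurr1 minus Hes5 were lost. Dopamine neuron genes differed by 2.13 (2.29e-09, 0.125 with an estimated correlation), GABA neuron genes by -3.86 (1.30e-06, 0.0506 with an estimated correlation) and serotonergic genes by -2.58 (4.28e-07, 0.125 with an estimated correlation). The count of 7 was 139 without Pitx3 positive replicate 1, 38 and 16 without Hes5 negative and positive replicate 2, and 0 without Pitx3 positive replicate 2 or 3 or Pitx3 negative replicate 3. It was 1 without any of the other 4 Hes5 arrays, 2 without Pitx3 negative replicate 2, 4 without Nurr1 positive replicate 1, and 1 without Nurr1 positive replicate 2 or any 1 Nurr1 negative array. The paired count of 414 was 240, 655 and 0 without Hes5 pairs 1, 2 and 3, 0 and 247 without Nurr1 pairs 2 and 3, and 658, 0 and 0 without Pitx3 pairs 1, 2 and 3.

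The Y-linked gene Eif2s3y was detected in 0 of 6 Nurr1 arrays, 6 of 6 Pitx3 arrays and 4 of 6 Hes5 arrays, with means of 4.56, 8.64 and 6.48. Of the 3 probes of the Y-linked gene Ddx3y, 1 was detected in all 18 arrays, with means of 8.36, 9.54 and 9.07 in these lines, and the other two in 0.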
